A study of Homo sapiens with 12 samples.

How the data were processed

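RNA was measured in 12 libraries of IMR90 ER:RAS fibroblasts, 4 per group, made with the Smart-Seq2 method for full-length cDNA and the Nextera XT kit, per the labels' protocols. The deposited table holds raw counts of reads per gene, whole numbers that the authors had not normalised. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.11 and featureCounts 1.18.0 were used with the hg19 and GRCh37 builds. Filters, the strand setting and the treatment of reads with several matches are not given in the sources used here. The kit does not mark strand, so antisense and overlapping genes, and near-identical copies, are uncertain. The libraries carry no molecular identifiers.

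Samples were grouped by the treatment in their labels, and each column was matched to its sample by name. Of 62069 gene identifiers, 50127 were matched to a symbol and 30032 had at least 1 read. Identifiers without a symbol held 0.488% of reads and stayed in the tests. Gene names came from a table of the GRCh38 assembly, which is not the authors' build, so no coordinates are given. Of 712 entries of the gene lists, 697 were matched.

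Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM, and fitted in 1 quasi-likelihood model of all 12 libraries with 3 groups and 9 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Log values used a prior count of 2. The 28 gene lists, 3 of them markers of other cell types, were tested with camera in limma 3.58.1 with a correlation of 0.01, with an estimated correlation, and with fry. The adjusted p of a list is from camera with Benjamini-Hochberg adjustment. They cover SASP cytokines, proteases and growth factors, NF-kB and p53 targets, CDK inhibitors, replication, mitosis, lamina and HMG proteins, RAS-ERK, interferon, matrix, methionine and folate, histone methyltransferases and demethylases, histones, ATF4, ER chaperones, cholesterol, lysosome, glycolysis, ribosomal proteins, ribosome biogenesis, respiratory chain, mitochondrial mRNAs, nuclear-retained RNAs, and epithelial, endothelial and immune markers.

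The groups, tests, lists and most alternatives were chosen before the data were examined. The rule for named genes took 11 fixed genes, the 5 highest and 5 lowest log2 fold changes with average log2 CPM above 1 and no overlap between groups, up to 4 members of each list, and the 5 (opposite) or 3 (same direction) largest changes shared by the first pair of comparisons. Genes outside the rule are named as such. For a gene with no read in a group, fold changes were bounded with 3 reads over the group, and for 1 to 3 reads a ratio is given with its 95% exact interval.

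Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals, no filter on low counts, a mean CPM of at least 1, the 8 libraries compared, an adjusted p under 0.01, and each library left out in turn. With no filter on low counts, camera compared each list with 30032 genes in place of 13248, many of them with few reads. List calls in that setting are therefore not like those of the main fit. A GC correction, that correction without library 31, and thinning to 9451160 reads were added after the data were seen. The GC correction removed a loess trend (span 0.4) of log2 CPM over transcript GC content, known for 12989 genes (98.0%).

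The steps were tested on simulated counts of 13248 genes. For 4OHT against DMSO, edgeR recovered 59.7%, 70.1% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 8 false calls. For 4OHT+3DA against 4OHT these were 56.7%, 85.1% and 95.5%, with 8 false calls, and for 4OHT+3DA against DMSO 52.2%, 83.6% and 95.5%, with 10. A changed list was called in each comparison and 0 of 20 unchanged lists by camera. Genes were simulated independently of each other, so this does not test false calls of lists whose members vary together. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots.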

Results

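Gene expression was measured in IMR90 ER:RAS cells, human fetal lung fibroblasts that carry a RAS oncogene fused to part of the oestrogen receptor, so that 4-hydroxytamoxifen (4OHT) switches the RAS protein on. The 12 RNA-seq libraries formed 3 groups of 4. Libraries 17 to 20 came from cells given the solvent DMSO, which the series design names non-senescent. Libraries 21 to 24 came from cells given 4OHT at 100 nM, named senescent there. Libraries 29 to 32 came from cells given 4OHT and 3-deazaadenosine (3DA), an adenosine analogue known to inhibit S-adenosylhomocysteine hydrolase, the enzyme encoded by AHCY. All cells were at passage 15 and day 6. The dose of 3DA and the day it was added are not given in the sources used here.

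Total counts ran from 9451160 to 19291493 reads per library, with group means of 11.3 M reads for DMSO, 13.8 M for 4OHT and 17.1 M for 4OHT+3DA. Of 62069 gene identifiers, 13248 passed the filter on low counts and were tested. Within a group, libraries had a Spearman correlation across genes of at least 0.982, and all 18 pairs of replicates differed by more than counting noise (chi-square per degree of freedom of 3.16 to 42.6). The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The first principal component held 62.0% of the variance and separated DMSO from both other groups. The second held 13.3% and separated 4OHT from 4OHT+3DA. Expression is given as CPM, counts scaled to the effective library size, as the mean ± SD of 4 libraries per group. Intervals and lower limits cover counting error only.

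**Figure D1:**
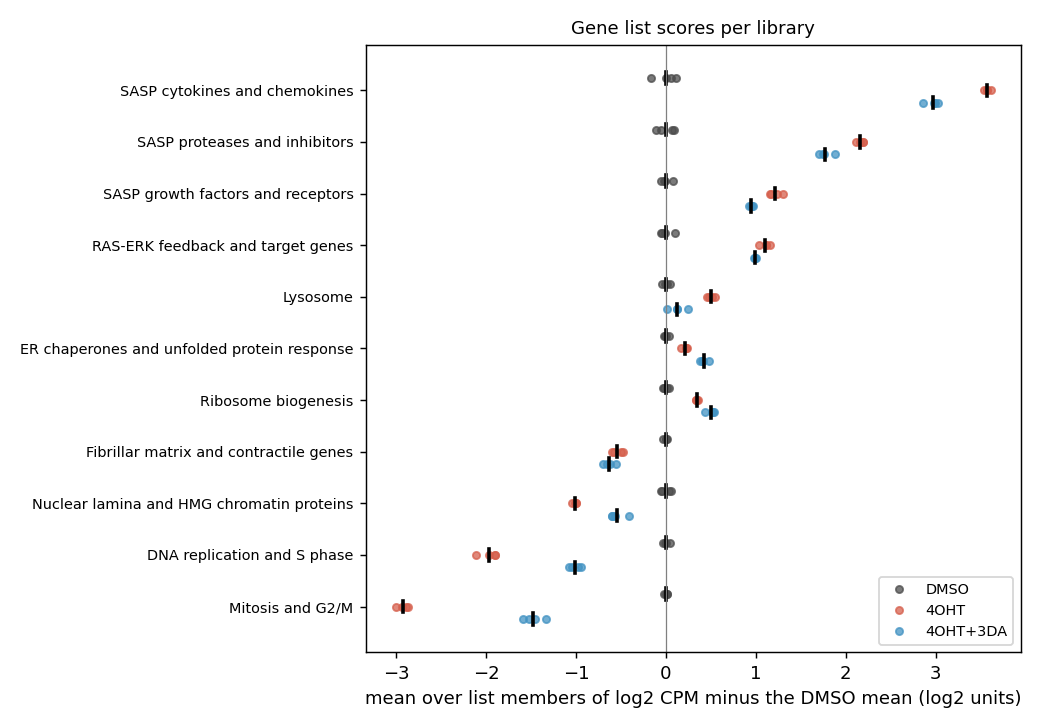
Scores of 11 gene lists fixed before the data were examined, as the mean over members of the log2 CPM minus the DMSO mean, with points for libraries coloured by group and black bars for the mean of 4 libraries. Mitosis scores lay lowest with 4OHT, with 4OHT+3DA between 4OHT and DMSO.

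The comparison of 4OHT with DMSO asks what changed when 4OHT switched RAS on in these fibroblasts. No cells without ER:RAS were given 4OHT here, so effects of 4OHT itself cannot be told apart from those of RAS. Inflammatory genes of the senescence-associated secretory phenotype (SASP) rose and genes of cell division fell. IL1B (ENSG00000125538), an inflammatory cytokine, went from 0.356 ± 0.213 CPM to 139.6 ± 13.1 CPM (n = 4 each; log2 fold change 8.51, SE 0.18). CXCL8 (ENSG00000169429), which attracts neutrophils, went from 1.94 ± 0.462 to 191 ± 13.0 CPM (log2 fold change 6.63, SE 0.13). The proliferation marker MKI67 (ENSG00000148773) fell from 28.3 ± 2.49 to 2.03 ± 0.974 CPM (log2 fold change −3.74, SE 0.22). LMNB1 (ENSG00000113368), encoding lamin B1 of the nuclear lamina, fell from 39.1 ± 0.796 to 2.68 ± 0.357 CPM (log2 fold change −3.86, SE 0.14).

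Of the 23 measured SASP cytokines and chemokines, 21 rose and 2 fell (the same counts when adjusted over the list alone), with a median log2 fold change of 4.43 (camera, Benjamini-Hochberg adjusted p = 4.6e-27). IL1A rose from 0.102 ± 0.0824 to 9.76 ± 1.26 CPM and IL6 from 0.813 ± 0.0591 to 3.85 ± 0.302 CPM. CSF3, the granulocyte growth factor, had 1 read in all DMSO libraries together and 1167 in the 4OHT libraries, a ratio of 1070 (95% counting interval 192 to 42262.5). CCL20 had no read with DMSO and was at least 106-fold higher with 4OHT, against a floor of 3 reads over the group. IL33 was likewise at least 33.6-fold higher. The exceptions CXCL12 (log2 fold change −3.26, SE 0.18) and IL15 (−1.62, SE 0.22) were named after their values were seen. With genes that had no DMSO read set at their lower limit, the median stayed at 4.43. Reads of the near-identical CXCL1, CXCL2 and CXCL3 may be shared between them.

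Of 18 SASP proteases and inhibitors, 16 rose and 2 fell (the same counts when adjusted over the list alone; median 1.58; camera adjusted p = 4.0e-36). The matrix-degrading MMP3 went from 17.3 ± 3.90 to 1944 ± 124 CPM, MMP1 from 709 ± 43.7 to 7081 ± 166 CPM and MMP10 from 0.349 ± 0.275 to 27.6 ± 3.14 CPM. TFPI2, a protease inhibitor, rose by a log2 fold change of 4.79 (SE 0.10). SERPINB4 had no DMSO read and was at least 31.8-fold higher, though its reads may be shared with SERPINB3. The metalloprotease inhibitors TIMP2 (−1.04, SE 0.10) and TIMP3 (−0.84, SE 0.089) fell, and were named after their values were seen. Among 27 SASP growth factors and receptors, 16 rose and 8 fell (the same counts when adjusted over the list alone; median 0.76; camera adjusted p = 3.0e-14). GDF15 rose from 42.0 ± 3.31 to 833 ± 25.9 CPM and BMP2 from 1.42 ± 0.422 to 56.5 ± 12.7 CPM. AREG, an EGF receptor ligand with 2 DMSO reads, was 95.4-fold higher (95% counting interval 26.4 to 787).

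Genes of the cell cycle fell as a block. All 40 mitosis and G2/M genes fell (the same counts when adjusted over the list alone; median −3.10; camera adjusted p = 6.2e-90). KIF20A, a kinesin of cell separation, fell from 94.5 ± 2.62 to 6.999 ± 0.929 CPM, the spindle gene DLGAP5 from 59.2 ± 4.42 to 4.70 ± 0.493 CPM and the kinetochore gene NDC80 from 43.1 ± 4.02 to 3.07 ± 0.469 CPM. Of 40 DNA replication and S phase genes, 39 fell (the same counts when adjusted over the list alone; median −1.88; camera adjusted p = 6.0e-37). Thymidine kinase TK1 (log2 fold change −3.41, SE 0.13), CCNE2 (−3.40, SE 0.29) and CDCA7 (−3.80, SE 0.18) were among them, and the cyclin gene CCNE1 alone rose (0.63, SE 0.15). Of 20 nuclear lamina and HMG chromatin genes, 16 fell and 2, HMGA1 and HMGA2, rose (the same counts when adjusted over the list alone; median −0.76; camera adjusted p = 1.7e-10). HMGB2 fell from 119 ± 14.7 to 14.1 ± 1.75 CPM and TMPO from 102 ± 6.86 to 29.5 ± 2.08 CPM, and both have processed pseudogenes that can take reads. HMGA2 rose by 0.77 (SE 0.10). The call of HMGA1 ended without single libraries (0.14 to 0.17 without DMSO 17, 18, 19 or 20 or 4OHT 21, 22 or 23) and its log2 fold change was 0.00329 with library totals.

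CDK inhibitors, which stop the cell cycle, split by member. CDKN1A (p21) rose from 1012 ± 22.5 to 2684 ± 75.2 CPM, CDKN2A (p16 and p14ARF, not separated) from 31.3 ± 0.637 to 72.3 ± 7.92 CPM and CDKN2B (p15) from 14.0 ± 0.839 to 179 ± 15.4 CPM. CDKN2C (log2 fold change −2.33, SE 0.38), CDKN1B (−1.42, SE 0.21) and CDKN3 (−3.23, SE 0.15) fell. The list of 8 was not called (median −0.41, with the camera direction higher; adjusted p = 0.226). Of 25 p53 targets, 12 rose (the same counts when adjusted over the list alone), among them PLK3 (log2 fold change 1.87, SE 0.090) and TIGAR (1.03, SE 0.11; camera adjusted p = 0.00167, but adjusted p = 0.0520 with an estimated correlation).

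HRAS reads, which can include reads of the introduced RAS and cannot be told apart from them, were higher with 4OHT at 2295 ± 130.3 CPM against 1610.1 ± 76.0 CPM (log2 fold change 0.51, SE 0.077). Feedback and target genes of the RAS-ERK pathway rose in 17 of 23 members (the same counts when adjusted over the list alone; median 1.01; camera adjusted p = 1.5e-12). DUSP6, a phosphatase that switches ERK off, went from 89.8 ± 3.40 to 619.5 ± 13.9 CPM, the ERK inhibitor SPRY2 from 24.7 ± 2.41 to 119 ± 6.37 CPM and the immediate early gene EGR1 from 37.4 ± 3.84 to 112 ± 8.14 CPM. Only FOSL1 fell (−0.72, SE 0.078), and it was named after its values were seen. AHCY, the target of 3DA, rose from 129 ± 4.53 to 174 ± 8.85 CPM. The list of the methionine, S-adenosylmethionine and folate cycle held 13 higher and 12 lower (the same when adjusted over the list alone) of 27 members and was not called (median −0.07, with the camera direction higher; adjusted p = 0.946).

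Lysosomal genes rose in 18 of 29 members, led by the cholesterol transporter NPC1 (27.2 ± 2.76 to 169 ± 14.4 CPM) and the protease CTSL (242 ± 9.96 to 911 ± 37.0 CPM), while FUCA1 and GUSB fell (the same counts when adjusted over the list alone; camera adjusted p = 1.9e-06, and adjusted p = 0.0563 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 24 members, such as NOP16 (log2 fold change 0.98, SE 0.076), and FBL fell, though its call ended in some settings (−0.24 to −0.18 without DMSO 17, 18 or 20 or 4OHT 23 or 24, −0.22 with no filter on low counts; the same counts when adjusted over the list alone; list adjusted p = 0.00334, and adjusted p = 0.0556 with an estimated correlation). Glycolysis and hypoxia genes were 14 higher and 4 lower (15 higher and 4 lower when adjusted over the list alone) of 25, with HK2 at 118 ± 9.05 CPM against 23.8 ± 1.30 CPM (camera adjusted p = 0.00193, and adjusted p = 0.336 with an estimated correlation). All 13 mitochondrially encoded mRNAs were higher (the same counts when adjusted over the list alone; median 0.62; adjusted p = 7.2e-06, and adjusted p = 0.250 with an estimated correlation), with MT-ND2 at 1187 ± 55.3 against 621 ± 37.2 CPM. Nuclear copies of these genes can share their reads.

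Fibrillar matrix and contractile genes fell in 22 of 31 members (5 higher and 23 lower when adjusted over the list alone; median −0.51; camera adjusted p = 7.6e-08, and adjusted p = 0.0563 with an estimated correlation). The proteoglycan DCN fell from 717 ± 21.5 to 109.8 ± 9.62 CPM, and the contractile genes TAGLN and CNN1 had log2 fold changes of −2.04 (SE 0.078) and −1.997 (SE 0.12). The 5 that rose were POSTN (96.4 ± 6.27 to 376 ± 35.8 CPM), TGFBI, COL5A3, TNC and COL6A3, whose call ended without single libraries (0.16 to 0.18 without DMSO 20 or 4OHT 24) and with library totals (0.0547). Interferon response genes were 6 higher and 15 lower (6 higher and 17 lower when adjusted over the list alone) of 27, with OAS3 (−2.72, SE 0.29) and IFIT2 (−2.42, SE 0.23) lower and CMPK2 (4.38, SE 0.52) higher. Their list was called (adjusted p = 0.0454), but adjusted p = 0.296 with an estimated correlation, and the call ended without 4OHT library 23 or 4OHT+3DA library 29 or 31 (medians −0.64 to −0.54), with library totals (−0.77) or with a GC correction (−0.60). NF-kB feedback targets are genes that this inflammatory factor switches on, and only some of them restrain it. Of 17 members, 6 were higher and 3 lower (the same when adjusted over the list alone). The list was called (camera adjusted p = 0.0461), but not with an estimated correlation (adjusted p = 0.208). Its call also ended with a mean CPM of at least 1 required or with a GC correction (median 0.09). BCL2A1 went from 0.228 ± 0.168 to 26.3 ± 2.14 CPM and IER3 from 35.5 ± 1.86 to 179 ± 13.5 CPM. BIRC3, CEBPD and REL were the lower ones. The call of REL ended in some settings (−0.85 to −0.63 without DMSO 17, 19 or 20 or 4OHT 22, 23 or 24, −0.79 with DESeq2, −0.78 with no filter on low counts, −0.74 with a GC correction, −0.75 after thinning).

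Markers of other cell types were measured beside these groups, but most of those listed were not tested. Only 7 of 20 epithelial, 5 of 14 endothelial and 3 of 17 immune markers passed the filter on low counts. Of 7 epithelial markers, KRT15 rose and KRT19, CLDN4 and KRT8 fell (the same counts when adjusted over the list alone; median −0.53; camera adjusted p = 0.0171, and adjusted p = 0.0890 with an estimated correlation), with KRT19 at 3.09 ± 0.660 against 58.7 ± 7.01 CPM. The call of this list ended with no filter on low counts (median −0.05, adjusted p = 0.167). Of 5 endothelial markers, TIE1, ROBO4 and EGFL7 rose (3 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.172). That list was called with no filter on low counts (median 1.04, adjusted p = 0.0276). Of 3 immune markers, FCER1G and CSF1R rose and CORO1A fell (the same counts when adjusted over the list alone; list adjusted p = 0.741). CORO1A stood at 3.56 ± 0.940 against 8.37 ± 1.49 CPM, and the call of CSF1R ended without DMSO library 19 or 20 (log2 fold change 1.19 to 1.23).

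Other lists were not called in this comparison, though some were with no filter on low counts. Histone genes of the replication-dependent clusters, which share near-identical copies, were 8 higher and 5 lower (the same when adjusted over the list alone) of 16: H4C3 fell by 3.04 on the log2 scale and H4C8 rose by 2.32 (list adjusted p = 0.0986, and the list was called higher with a mean CPM of at least 1 required, median 0.85). Histone lysine methyltransferases and demethylases were 6 higher and 15 lower (the same when adjusted over the list alone) of 32 (adjusted p = 0.0986), with EZH2 at 5.94 ± 0.664 against 29.2 ± 2.20 CPM. The ATF4 amino acid response was 12 higher and 4 lower (13 higher and 4 lower when adjusted over the list alone) of 21 (adjusted p = 0.0543; the list passed without DMSO library 17 or 19, 4OHT library 22 or 23 or 4OHT+3DA library 30 or 32, with medians of 0.32 to 0.40). ER chaperones were 11 higher and 2 lower (the same when adjusted over the list alone) of 20 (adjusted p = 0.186) and cholesterol synthesis genes 5 higher and 6 lower (the same when adjusted over the list alone) of 23 (adjusted p = 0.762). Cytosolic ribosomal proteins were 17 higher (12 higher when adjusted over the list alone) of 53 (adjusted p = 0.0986) and nuclear-encoded respiratory chain genes 15 higher (the same when adjusted over the list alone) of 30 (adjusted p = 0.0802). Both of these lists passed without DMSO library 20 or 4OHT library 24, with medians of 0.24 and 0.24 for the ribosomal proteins and 0.25 and 0.23 for the respiratory chain. Nuclear-retained and immediate early RNAs were 6 higher and 3 lower (the same when adjusted over the list alone) of 12 (adjusted p = 0.168). With no filter on low counts, the histone methyltransferases and demethylases were called lower (median −0.24, adjusted p = 0.00746). Called higher in that setting were the histone genes (median 0.47, adjusted p = 0.0110), the ATF4 response (median 0.37, adjusted p = 5.8e-04) and ER chaperones (median 0.23, adjusted p = 0.00522). So were the ribosomal proteins (median 0.20, adjusted p = 4.6e-05), the respiratory chain (median 0.21, adjusted p = 4.1e-05) and the nuclear-retained RNAs (median 0.54, adjusted p = 0.0341).

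Outside the lists, the largest rises by the fixed rule included the long non-coding RNA LINC02392, with no DMSO read and at least 509-fold higher, and the elastase inhibitor PI3, at least 110-fold higher. LCE1F, a skin barrier gene, went from 0.0965 ± 0.138 to 89.9 ± 12.1 CPM. The largest falls included TOX (log2 fold change −5.00, SE 0.33), SLC7A14 (−4.92, SE 0.23), CEMIP (−4.88, SE 0.36) and the receptor gene KIT (−4.57, SE 0.26).

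Among the genes named for this comparison, MMP1, SPRY2, IL33 and those that went against the direction of their list, including CCNE1, HMGA1, HMGA2, FBL, FUCA1, GUSB, REL, TGFBI, COL5A3, COL6A3 and TNC, were chosen after their values were seen.

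In all, 6889 of 13248 tested genes differed between 4OHT and DMSO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 3511 higher and 3378 lower, of which 821 rose and 1317 fell by more than 2-fold. The 4 libraries of either group did not overlap for 6817 genes, 51.5% of those tested, where chance gives 2.86%. Nor did they for 117 of the 119 called genes named for this comparison. The rule chose named genes partly for large changes and no overlap, so their count adds no support. List scores did not overlap between the groups for any of the 16 lists called by camera. With library totals in place of TMM factors, the median log2 fold change of all genes shifted to −0.167 and the calls split into 2385 higher and 4727 lower.

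**Figure D2:**
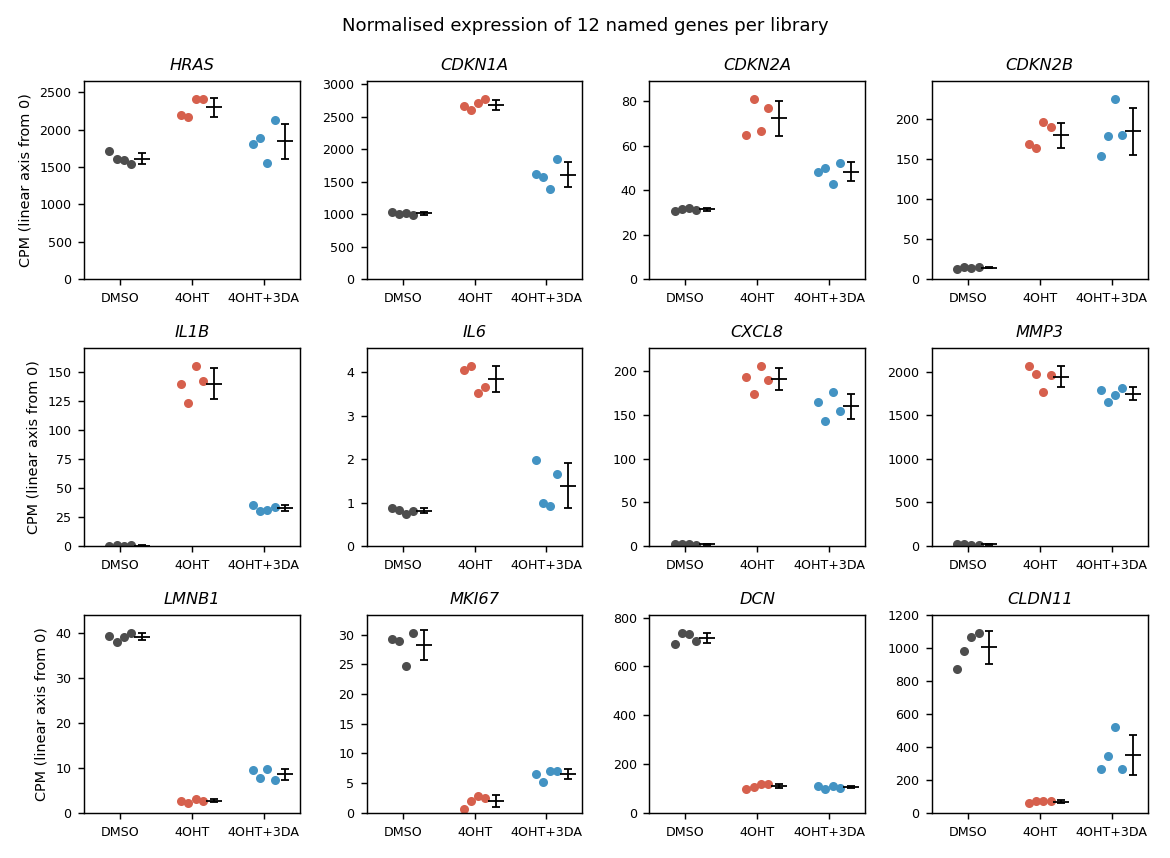
CPM per library of 12 named genes on linear axes that start at 0, with points for libraries coloured by group and bars that show the mean and SD of 4 libraries. IL1B stood at 139.6 CPM with 4OHT and 32.4 CPM with 4OHT+3DA, while CDKN2B stood at 179 and 184 CPM.

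The comparison of 4OHT+3DA with 4OHT asks what 3DA changed in cells with active RAS. No group was given 3DA alone. Cell division genes rose and many inflammatory genes fell. MKI67 rose from 2.03 ± 0.974 to 6.47 ± 0.851 CPM (n = 4 each; log2 fold change 1.61, SE 0.23) and LMNB1 from 2.68 ± 0.357 to 8.57 ± 1.24 CPM (1.67, SE 0.14). IL1B fell from 139.6 ± 13.1 to 32.4 ± 2.598 CPM (−2.11, SE 0.10) and IL6 from 3.85 ± 0.302 to 1.39 ± 0.519 CPM (−1.48, SE 0.26). CDKN1A fell from 2684 ± 75.2 to 1606 ± 189 CPM (−0.74, SE 0.069).

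Of 40 mitosis and G2/M genes, 39 rose (the same counts when adjusted over the list alone; median 1.54; camera adjusted p = 9.5e-89). CDK1, the kinase that starts mitosis, rose from 8.92 ± 2.54 to 41.8 ± 13.0 CPM, DLGAP5 from 4.70 ± 0.493 to 21.9 ± 4.61 CPM and TTK from 5.48 ± 1.38 to 23.9 ± 7.77 CPM. Of 40 replication genes, 33 rose (34 higher when adjusted over the list alone; median 0.88; camera adjusted p = 2.5e-35), with CCNE2 at 4.08 ± 1.35 against 0.792 ± 0.335 CPM and MCM10, a replication initiation gene, at 8.80 ± 1.13 against 2.58 ± 0.901 CPM. Of 20 nuclear lamina and HMG chromatin genes, 11 rose (11 higher and 1 lower when adjusted over the list alone; median 0.29; camera adjusted p = 7.9e-08). HMGB1 and TMPO, which have pseudogenes, and SUV39H2 had log2 fold changes of 0.93, 1.176 and 0.97 (SE 0.10, 0.11 and 0.16). All 72 called members of the mitosis and replication lists were also called with a GC correction and without 4OHT+3DA library 31, which stood apart in a trend over transcript GC content (Spearman correlation −0.542).

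SASP cytokines and chemokines fell in 14 of 23 members and rose in 4 (14 and 6 when adjusted over the list alone; median −0.56; camera adjusted p = 5.2e-09). CSF3 fell from 22.4 ± 2.04 to 3.91 ± 0.356 CPM, CCL20 from 6.63 ± 0.977 to 1.30 ± 0.145 CPM, IL24 from 4.96 ± 0.691 to 0.921 ± 0.347 CPM and IL1A from 9.76 ± 1.26 to 4.27 ± 0.514 CPM. CXCL8 fell from 191 ± 13.0 to 159.7 ± 14.2 CPM, and its call ended without single libraries (−0.26 to −0.21 without 4OHT 21, 23 or 24 or 4OHT+3DA 30 or 32), with library totals (−0.20) and with no filter on low counts (−0.23). The 4 that rose were CXCL12 (1.801, SE 0.19), CXCL6 (1.90, SE 0.48), CXCL3 (0.53, SE 0.11) and IL33 (0.81, SE 0.26), named after their values were seen. The call of IL33 ended without single libraries (0.71 to 0.80 without 4OHT 21, 22 or 23 or 4OHT+3DA 29 or 31) and with a GC correction (0.44, and 0.55 also without library 31).

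Among 18 SASP proteases and inhibitors, 9 fell and 2 rose (9 and 3 when adjusted over the list alone; camera adjusted p = 5.4e-05, and adjusted p = 0.0592 with an estimated correlation). ADAMTS1 fell from 359 ± 21.3 to 181 ± 10.2 CPM and CTSB from 3974 ± 83.2 to 2338 ± 238 CPM. SERPINB4 had 3 reads in all libraries with 3DA and was 45.0-fold lower (95% counting interval 15.4 to 218). TFPI2 (0.39, SE 0.084) and SERPINE2 (0.27, SE 0.076; not called without 4OHT library 22, 0.22) rose, named after their values were seen. MMP3 stood at 1749 ± 74.6 against 1944 ± 124 CPM and did not pass the test (−0.15, SE 0.092). Of 27 growth factors and receptors, 12 fell and 3 rose (12 and 5 when adjusted over the list alone; camera adjusted p = 8.1e-04). The adhesion molecule gene ICAM1 fell from 56.1 ± 8.34 to 10.8 ± 1.70 CPM and GDF15 from 833 ± 25.9 to 468 ± 44.5 CPM, while HGF (0.93, SE 0.089), STC1 (0.32, SE 0.054) and TNFRSF11B (0.32, SE 0.071) rose.

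NF-kB feedback targets fell in 9 of 17 members (the same counts when adjusted over the list alone; median −0.54; camera adjusted p = 2.6e-06). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, had a log2 fold change of −0.90, SE 0.079, and TNFAIP3 fell from 7.62 ± 1.37 to 2.76 ± 0.527 CPM. Lysosomal genes fell in 18 of 29 members (1 higher and 21 lower when adjusted over the list alone; median −0.32; camera adjusted p = 3.0e-09), with SQSTM1, an autophagy receptor, at 529.8 ± 57.2 against 1044 ± 23.8 CPM and CTSS at 4.502 ± 1.79 against 11.7 ± 0.332 CPM, and GUSB rose. Genes of the ATF4 amino acid response fell in 11 of 21 members (2 higher and 11 lower when adjusted over the list alone; camera adjusted p = 4.1e-05, and adjusted p = 0.0531 with an estimated correlation), with DDIT3 at 23.9 ± 1.90 against 45.1 ± 2.25 CPM. ER chaperones rose in 12 of 20 members (13 higher and 1 lower when adjusted over the list alone; median 0.29; camera adjusted p = 0.00134), such as PDIA4 (0.42, SE 0.064), MANF (0.42, SE 0.089) and SDF2L1 (0.57, SE 0.10). Their single lower member, HERPUD1, lost its call in some settings (−0.20 to −0.16 without 4OHT 22 or 4OHT+3DA 30, −0.14 with library totals, −0.17 with no filter on low counts, −0.19 in a fit of the 8 libraries compared).

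HRAS reads were at 1844 ± 237 CPM with 3DA against 2295 ± 130.3 CPM (log2 fold change −0.32, SE 0.077; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00518). The RAS-ERK list was not called (median −0.15; camera adjusted p = 0.0754), with 4 higher and 7 lower (4 higher and 9 lower when adjusted over the list alone) of 23 members. It was called lower with no filter on low counts (median −0.12, adjusted p = 0.0209). The fry test, which asks whether members shifted in a common direction, leaving other genes aside, called it too (adjusted p = 0.000109). That test called 22 of 28 lists here. ETV4 fell (−0.74, SE 0.12) and PHLDA1 (0.75, SE 0.11), MYC (0.37, SE 0.079), SPRED1 (0.58, SE 0.15) and EGR3 were higher. The call of EGR3 ended in some settings (0.83 to 1.25 without DMSO 17, 19 or 20 or 4OHT 22, 23 or 24 or 4OHT+3DA 30 or 31, 1.17 with DESeq2, 1.179 in a fit of the 8 libraries compared, 0.87 with a GC correction and without library 31, 1.23 after thinning). DUSP6 did not pass the test (0.10, SE 0.074). AHCY did not pass it either (log2 fold change −0.05, SE 0.080; 0.0120 with library totals, 0.0243 with a GC correction and 0.0199 without library 31), and neither did CDKN2B (0.04, SE 0.095; −0.0693 without library 31), while CDKN2A fell (−0.58, SE 0.088) and CDKN3 rose (1.47, SE 0.15; list of 8, median −0.08, adjusted p = 0.427). In the methionine and folate list, 7 of 27 members were higher and 3 lower (8 and 3 when adjusted over the list alone; adjusted p = 0.371). With no filter on low counts that list was called higher (median 0.11, adjusted p = 0.0357). MTAP, which salvages methionine, rose from 84.0 ± 6.57 to 149 ± 37.1 CPM and NNMT, a user of S-adenosylmethionine, fell from 23.6 ± 0.415 to 10.3 ± 0.880 CPM.

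Of 31 matrix and contractile genes, 10 fell and 6 rose (12 and 6 when adjusted over the list alone). COL1A2, a chain of collagen type I, fell from 1255 ± 77.1 to 860.5 ± 63.0 CPM and LUM from 48.4 ± 2.88 to 25.5 ± 3.16 CPM, while POSTN rose (0.64, SE 0.11) and DCN did not pass the test (−0.06, SE 0.070), but was called lower with a GC correction (−0.19). The list was called lower (median −0.16; camera adjusted p = 0.0393), with adjusted p = 0.419 with an estimated correlation, and the call ended with library totals, with a GC correction, with that and without library 31, and without 4OHT library 23 or 24 or 4OHT+3DA library 29, 30 or 31 alone (medians −0.12 to −0.08). Ribosome biogenesis genes rose in 7 of 24 members, with NOLC1 at 159.5 ± 5.77 against 97.2 ± 9.25 CPM (the same counts when adjusted over the list alone; adjusted p = 0.0122, and adjusted p = 0.0890 with an estimated correlation). Cytosolic ribosomal proteins, many with pseudogenes, fell in 17 of 53 members (19 lower when adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.540 with an estimated correlation), for example RPS28 (−0.49, SE 0.12). Mitochondrially encoded mRNAs fell in 5 of 13 members (7 lower when adjusted over the list alone; adjusted p = 0.00497, and adjusted p = 0.419 with an estimated correlation), with MT-ND1 at 988 ± 142 against 1318 ± 92.4 CPM. Endothelial markers fell in 2 of 5, ROBO4 (−1.22, SE 0.17) and TEK (−1.50, SE 0.23; the same counts when adjusted over the list alone; list adjusted p = 0.00454, and adjusted p = 0.0531 with an estimated correlation).

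The remaining lists were not called. The interferon list had a median and a mean of opposite sign (adjusted p = 0.979), and 5 of its 27 members passed, with USP18 (0.40, SE 0.10), IRF9 and SAMD9 higher and IFIT3 and CXCL10 lower. Those calls ended in some settings for IRF9 (1.05 to 1.31 without 4OHT 23 or 24 or 4OHT+3DA 29, 31 or 32, 1.30 with DESeq2, 1.31 with no filter on low counts, 1.13 with a GC correction and without library 31), SAMD9 (0.39 to 0.60 without 4OHT 22 or 23 or 4OHT+3DA 31, 0.25 with a GC correction, 0.19 with a GC correction and without library 31), IFIT3 (−0.36 without 4OHT+3DA 30) and CXCL10 (−1.27 to −1.01 without 4OHT 22 or 24 or 4OHT+3DA 30, −1.25 with no filter on low counts). Of 25 p53 targets, 7 fell and FDXR, CCNG1 and SESN1 were higher (adjusted p = 0.121). The call of SESN1 ended in some settings (0.23 to 0.33 without 4OHT 21 or 23 or 4OHT+3DA 31, 0.17 with a GC correction, 0.15 with a GC correction and without library 31). Histone methyltransferases and demethylases were higher in 7 of 32, EZH2 among them (0.63, SE 0.12), and lower in EZH1 and KDM4C (adjusted p = 0.203). The call of KDM4C ended in some settings (−0.31 to −0.26 without DMSO 18 or 4OHT 21, 22, 23 or 24 or 4OHT+3DA 30, 31 or 32, −0.24 with library totals, −0.27 with no filter on low counts, −0.25 with a GC correction and without library 31, −0.20 after thinning). Replication-dependent histone genes (adjusted p = 0.488, with a median of 0.04 and the camera direction lower), cholesterol genes (0.192), the respiratory chain (0.189) and immune markers (0.946) also missed the threshold. So did glycolysis genes (adjusted p = 0.112; called without 4OHT+3DA library 32, median −0.11) and immediate early RNAs (adjusted p = 0.121; called without 4OHT+3DA library 31, median −0.14, and −0.11 with a GC correction too). With no filter on low counts, glycolysis genes (median −0.10, adjusted p = 0.0341) and immediate early RNAs (median −0.10, adjusted p = 0.0357) were called lower. The histone methyltransferases and demethylases (median 0.11, adjusted p = 0.0131) and cholesterol genes (median 0.12, adjusted p = 0.00801) were called higher in that setting. Of 7 epithelial markers KRT18 alone fell (list adjusted p = 0.189). Its call ended in some settings (−0.28 to −0.26 without 4OHT 21 or 22, −0.24 with library totals, −0.27 with no filter on low counts, −0.20 with a GC correction and without library 31).

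Outside the lists, the genes with the largest falls by the fixed rule included PI3 (6.90 ± 0.911 to 0.413 ± 0.205 CPM), LINC02392 (32.4 ± 4.43 to 3.25 ± 0.710 CPM), C15orf48 (8.36 ± 1.07 to 1.08 ± 0.255 CPM) and ANKRD1 (8.91 ± 2.08 to 1.31 ± 0.299 CPM). DEPDC1 (2.80, SE 0.20), the kinetochore gene KNL1 (2.39, SE 0.23), the tight junction gene CLDN11 (2.36, SE 0.16) and the recombination gene MND1 (2.36, SE 0.38) were among the largest rises. PDE7B-AS1, an antisense RNA whose reads cannot be told from those of its partner, fell (−2.55, SE 0.23).

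Among the genes named for this comparison, MMP3, DUSP6, DCN, MYC, SPRED1, STC1, TNFRSF11B, USP18, SESN1, KDM4C, HERPUD1 and GUSB were chosen after their values were seen.

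Here 3558 of 13248 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1909 higher and 1649 lower, and 297 rose and 234 fell by more than 2-fold. The groups did not overlap for 3311 genes, 24.99% of those tested (2.86% by chance), nor for the scores of 12 of the 15 lists called. They did not overlap for 95 of the 103 called genes named for this comparison, which the rule partly fixed in advance. The 8 that overlapped were CCNG1, CXCL8, EGR3, GCHFR, IL33, MT-ND1, RPS28 and SAMD9. The 4OHT+3DA libraries varied more in a trend over transcript GC content. The Spearman correlation across genes between GC content and the deviation from the mean of all libraries was −0.244 in library 30. It was −0.00327 in library 29 and 0.151 in library 32, besides the value given for library 31. In the 4OHT libraries it ran from 0.121 to 0.155. Genes called higher made up 32.1% of the lowest of 5 equal bins by GC content and 5.39% of the highest. Without library 31 there were 1686 higher and 1557 lower calls, and 1488 of the 1909 higher calls were kept. With library totals the median of all genes shifted to 0.0652 and the calls split into 2535 higher and 1207 lower.

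**Figure D3:**
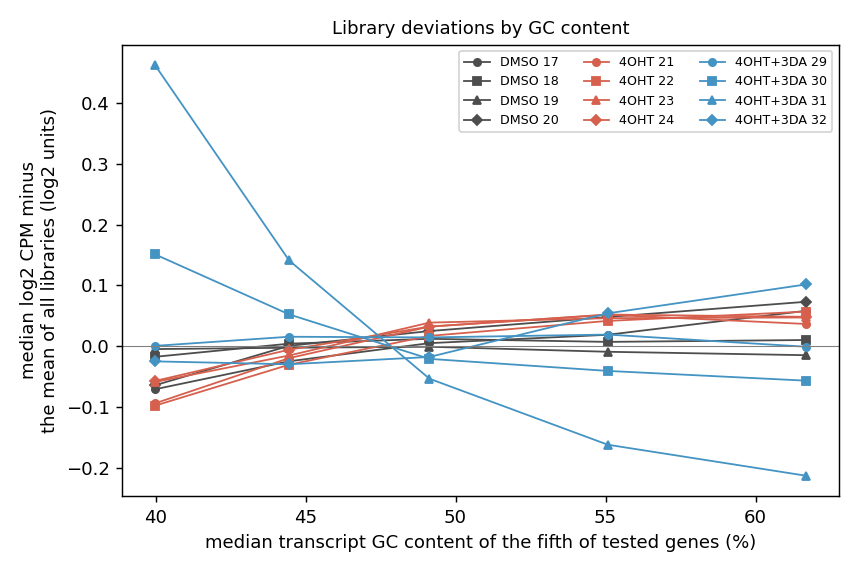
Median deviation of each library from the mean of all 12 libraries, in log2 CPM, for 5 equal bins of the tested genes by transcript GC content, with a line per library that carries its replicate number and is coloured by group. Library 31 of 4OHT+3DA ran from 0.462 in the lowest bin to −0.212 in the highest.

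Changes under 4OHT and under 3DA were next set against each other. Of the genes called in both comparisons, 1835 moved in opposite directions, 902 higher with 4OHT then lower with 3DA and 933 the other way. Independent lists of these sizes would share 437 and 487 genes. Another 519 moved in the same direction, 249 higher in both and 270 lower in both, where independent lists would share 506 and 420. ICAM1 (1.27 then −2.39), IL1B (8.51 then −2.11) and CLDN11 (−3.87 then 2.36) were examples of opposite log2 fold changes. IQGAP2 (1.99 then 1.27) and PRKG2 (2.02 then 1.25) rose in both, as did GNG11, at 220.4 ± 35.1, 662 ± 36.7 and 1324 ± 591 CPM with DMSO, 4OHT and 4OHT+3DA. The cytokine gene IL32 (−2.19 then −1.85), GCHFR (−1.43 then −1.43) and the pseudogene WFDC21P (−2.45 then −2.20) fell in both. For GCHFR the 4OHT and 4OHT+3DA libraries overlapped.

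The 4OHT libraries enter both comparisons with opposite signs, so a negative relation arises with no effect at all. The Pearson correlation of the log2 fold changes across genes, which are not independent replicates, was −0.451, and −0.515 in 50 simulations of unchanged groups. The covariance was −0.186 against −0.0207 simulated. With the 4OHT libraries split between the comparisons in all 6 ways, the mean correlation was −0.377 (−0.00141 simulated) and the mean covariance −0.165 (−8.9e-05 simulated, range −0.00244 to 0.00124). The splits gave on average 1061 genes called in opposite directions and 258 in the same direction, where independent lists would give 433 opposite. In these splits, genes more than 2-fold higher in 2 of the 4OHT libraries had a median log2 fold change over DMSO of 1.66 in the other 2 and 1.40 in 4OHT+3DA. For genes more than 2-fold lower these medians were −1.56 and −1.28.

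**Figure D4:**
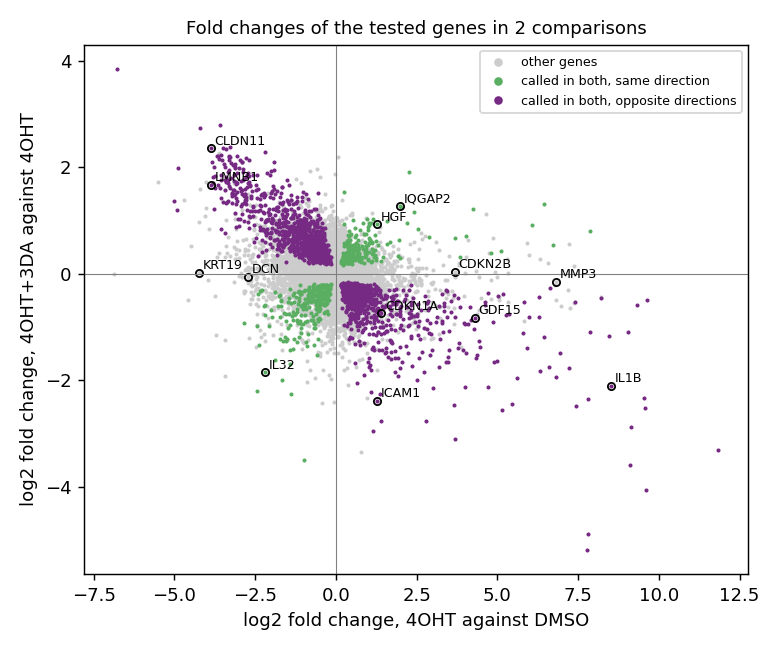
Log2 fold changes of the 13248 tested genes for 4OHT against DMSO (horizontal) and 4OHT+3DA against 4OHT (vertical), with purple points for the 1835 genes called in both in opposite directions, green points for the 519 called in the same direction, and circles for named genes. Points at the far right include genes with no DMSO read, whose fitted value depends on the prior count.

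The comparison of 4OHT+3DA with DMSO asks how far cells with both treatments stood from cells with neither. SASP genes were still far above DMSO and cell division genes below it. IL1B stood at 32.4 ± 2.598 CPM against 0.356 ± 0.213 CPM (n = 4 each; log2 fold change 6.402, SE 0.20), CXCL8 at 159.7 ± 14.2 against 1.94 ± 0.462 CPM (6.37, SE 0.13) and MMP3 at 1749 ± 74.6 against 17.3 ± 3.90 CPM (6.65, SE 0.12). MKI67 was at 6.47 ± 0.851 against 28.3 ± 2.49 CPM (−2.13, SE 0.18) and LMNB1 at 8.57 ± 1.24 against 39.1 ± 0.796 CPM (−2.19, SE 0.12). CDKN2B was at 184 ± 29.5 against 14.0 ± 0.839 CPM (3.72, SE 0.11), CDKN1A at 1606 ± 189 against 1012 ± 22.5 CPM (0.67, SE 0.069) and CDKN2A at 48.3 ± 4.16 against 31.3 ± 0.637 CPM (0.63, SE 0.091).

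Higher than DMSO were 19 of 23 SASP cytokines and chemokines (20 higher and 2 lower when adjusted over the list alone; median 4.16, the same with zero-count genes at their limit; camera adjusted p = 1.9e-20), with CXCL12 and IL15 lower. IL6 did not pass the test at 1.39 ± 0.519 against 0.813 ± 0.0591 CPM (log2 fold change 0.75, SE 0.31), but it did without 4OHT+3DA library 30 (0.89) or 31 (0.90). It also passed after thinning (0.904) and with a GC correction and without library 31 (0.91). IL33 was at least 58.5-fold higher and CCL20 at least 20.98-fold higher, with no DMSO read for either. SASP proteases were higher in 13 and lower in 3 of 18 (the same counts when adjusted over the list alone, camera adjusted p = 2.8e-30). Growth factors were higher in 14 and lower in 8 of 27 (15 higher and 8 lower when adjusted over the list alone, camera adjusted p = 6.3e-11), with STC1 at 4129 ± 49.1 against 231 ± 14.5 CPM. RAS-ERK genes were higher in 17 and lower in 1 of 23 (the same counts when adjusted over the list alone, camera adjusted p = 2.0e-11), for example DUSP6 (2.89, SE 0.081). HRAS itself was at a log2 fold change of 0.20, SE 0.077, a call that ended without single libraries (0.12 to 0.19 without DMSO 18, 19 or 20 or 4OHT+3DA 30 or 32), with library totals (0.10), with a mean CPM of at least 1 required (0.18) and in a fit of the 8 libraries compared (0.17).

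All 40 mitosis genes (median −1.41; camera adjusted p = 7.9e-36) and 36 of 40 replication genes (median −1.04; adjusted p = 2.0e-14) were lower than in DMSO, the same counts as when adjusted over each list alone. CCNE1 was higher, a call that ended with library totals (0.34) and without single libraries (0.34 to 0.37 without DMSO 18 or 19 or 4OHT+3DA 32). Lamina and HMG genes were lower in 13 and higher in 4 of 20 (the same counts when adjusted over the list alone, camera adjusted p = 3.6e-05), with HMGB2 at −2.20 (SE 0.11). Matrix and contractile genes were lower in 22 and higher in 4 of 31 (the same counts when adjusted over the list alone, median −0.75, camera adjusted p = 1.5e-12), with DCN at 105 ± 5.63 against 717 ± 21.5 CPM. Epithelial markers were lower in 6 of 7 (1 higher and 6 lower when adjusted over the list alone; adjusted p = 5.8e-04), with KRT19 at 3.19 ± 0.821 CPM and EPCAM at 0.770 ± 0.0458 against 1.66 ± 0.318 CPM. Ribosome biogenesis genes were higher in 19 of 24 (the same counts when adjusted over the list alone; median 0.51; adjusted p = 2.6e-06), with NOLC1 (1.123, SE 0.076) and POLR1B (1.08, SE 0.091) among them, and ER chaperones in 15 of 20 (the same counts when adjusted over the list alone; median 0.37; adjusted p = 0.00117), with MANF (0.95, SE 0.091) and DNAJB9 (1.23, SE 0.17).

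Calls that were lost with an estimated correlation were those of p53 targets (adjusted p = 0.0112, and adjusted p = 0.0845 with an estimated correlation), the interferon list (0.0271, and adjusted p = 0.259 with an estimated correlation), glycolysis (0.0154, and adjusted p = 0.419 with an estimated correlation) and mitochondrially encoded mRNAs (0.00119, and adjusted p = 0.371 with an estimated correlation). The lysosome list was at the threshold (median 0.07; adjusted p = 0.0495, and adjusted p = 0.386 with an estimated correlation). Its call ended without DMSO library 17, 18 or 20, 4OHT library 21 or 4OHT+3DA library 29 or 32 (medians 0.00962 to 0.0863), with a mean CPM of at least 1 required (median 0.0628), and with library totals (median −0.03). NPC1 was at 105 ± 14.0 against 27.2 ± 2.76 CPM and SQSTM1 at 529.8 ± 57.2 against 634 ± 12.8 CPM. NF-kB targets (3 higher and 8 lower of 17; adjusted p = 0.924) were not called, with TNFAIP3 (−1.73, SE 0.21) and NFKBIA (−0.83, SE 0.080) lower than in DMSO. The ATF4 list (8 higher and 5 lower of 21; adjusted p = 0.946) was not called either, and its member STC2 (−2.02, SE 0.065) was lower. The methionine list (adjusted p = 0.618) had a median and a mean of opposite sign.

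Not called were CDK inhibitors (adjusted p = 0.488, with a negative median and mean and the camera direction higher), histone genes (0.164; called higher with a mean CPM of at least 1 required, median 0.77), histone methyltransferases and demethylases (0.246), cholesterol genes (0.757), cytosolic ribosomal proteins (0.710), the respiratory chain (0.223), immediate early RNAs (0.496), endothelial markers (0.946) and immune markers (0.677). With no filter on low counts, histone genes (median 0.40, adjusted p = 0.0153) and the respiratory chain (median 0.16, adjusted p = 0.00107) were called higher. CCNE1, CXCL12, IL15, NFKBIA and SQSTM1 were named here after their values were seen.

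In this comparison 6825 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 3572 higher and 3253 lower, and 727 rose and 1245 fell by more than 2-fold. Groups did not overlap for 5924 genes, 44.7% of those tested (2.86% by chance), and for the scores of 15 of the 16 called lists. They did not overlap for 70 of the 71 called genes named here, again partly fixed by the rule that chose them. Over all 3 comparisons camera called 47 lists, and 26 held with an estimated correlation. These were the 3 SASP lists, mitosis, replication, lamina and HMG, and RAS-ERK with 4OHT, and the same lists with matrix, ER chaperones, ribosome biogenesis and epithelial markers for 4OHT+3DA against DMSO. For 4OHT+3DA against 4OHT they were SASP cytokines, growth factors, NF-kB targets, mitosis, replication, lamina and HMG, ER chaperones and lysosome. With library totals the median of all genes shifted to −0.0888, with 2798 calls higher and 4035 lower.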

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

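The GC correction, its use without library 31 and the thinning were chosen after the data were seen, and both tests of a fixed share of cells were written after the result, that on the matrix list after the shares of all lists were seen. The tests of GC content and depth were set after the GC trend and the difference in depth had been seen, but before the shares of kept calls were.

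Of 651 groups of 4 libraries tested for 1 library far from its others, 35 (5.38%) stood out, where chance gives about 5%. By library these were most often in DMSO library 18, with 8. List scores that stood apart were methionine, SAM and folate cycle at −0.0412 in DMSO library 20 (others 0.0101 to 0.0191), histone genes of the replication-dependent clusters at 0.435 in 4OHT+3DA library 29 (others 0.0447 to 0.1004), ATF4 amino acid response at 0.321 in 4OHT library 23 (others 0.367 to 0.377), ER chaperones and unfolded protein response at 0.166 in 4OHT library 21 (others 0.223 to 0.234) and nuclear-retained and immediate early RNAs at 0.243 in 4OHT library 23 (others 0.363 to 0.377).

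In the DMSO group the values that stood apart were HK2 at 25.8 CPM in library 17 (others 23.1 to 23.3), ANKRD1 at 4.58 CPM in library 18 (others 2.79 to 2.96), CSF3 at 0.0751 CPM in library 18 (others 0 in each), DUSP4 at 3.45 CPM in library 18 (others 1.96 to 2.12), EGR3 at 0.375 CPM in library 18 (others 0.0734 to 0.0980), ENO2 at 64.1 CPM in library 18 (others 59.8 to 60.5), GDF5 at 8.86 CPM in library 18 (others 13.8 to 14.6), TFPI2 at 52.8 CPM in library 18 (others 46.6 to 47.5), TIGAR at 66.1 CPM in library 18 (others 57.9 to 58.3), CCNG1 at 332 CPM in library 19 (others 279 to 285), OAS3 at 14.5 CPM in library 20 (others 12.3 to 12.5) and SPRY2 at 28.2 CPM in library 20 (others 23.1 to 23.8).

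In the 4OHT group they were CDK1 at 5.13 CPM in library 21 (others 9.81 to 10.5), FUCA1 at 3.29 CPM in library 21 (others 4.77 to 5.07), PDE7B-AS1 at 5.80 CPM in library 21 (others 5.32 to 5.35), PDIA4 at 272 CPM in library 21 (others 294 to 298), CSF1R at 0.798 CPM in library 22 (others 1.73 to 1.84), DUSP6 at 599 CPM in library 22 (others 626 to 628), MYBL2 at 0.479 CPM in library 22 (others 0.193 to 0.207), IL32 at 3.80 CPM in library 23 (others 3.00 to 3.11) and KRT19 at 4.07 CPM in library 24 (others 2.69 to 2.87).

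In the 4OHT+3DA group they were EZH1 at 13.2 CPM in library 29 (others 9.47 to 9.97), REL at 1.68 CPM in library 29 (others 0.929 to 1.04), TNFRSF11B at 174 CPM in library 29 (others 200.02 to 204), GDF5 at 0.568 CPM in library 30 (others 0.749 to 0.780), IFIT3 at 6.97 CPM in library 30 (others 9.12 to 9.49), ETV4 at 13.6 CPM in library 31 (others 19.1 to 19.9), FUCA1 at 0.922 CPM in library 31 (others 2.28 to 2.56), NFKBIA at 44.6 CPM in library 32 (others 36.8 to 37.2) and SERPINB4 at 0.207 CPM in library 32 (others 0 in each).

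Of 35 splits of the 8 libraries in each comparison, only the real one called as many genes. The other splits mix the groups, so the group difference adds to their spread and few calls can arise. They therefore cannot exclude a chance difference between cultures that is unrelated to treatment. The real splits called 7669, 2851 and 6293 genes for 4OHT against DMSO, 4OHT+3DA against 4OHT and 4OHT+3DA against DMSO, and the highest of the 34 others called 0 in each.

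Genes called higher with 3DA made up 32.1% of the lowest of 5 equal bins by GC content and 5.39% of the highest. With the GC correction and without library 31, 100.0% of the 72 called members of the mitosis and replication lists stayed higher, which argues against the GC trend as the cause for those lists. Of all 1909 higher calls 1446 stayed with the correction alone (1863 called in all). With the correction and without library 31, 1270 (66.5%) stayed, between the bounds set for the trend. The calls kept count against the trend as the whole cause. Without the correction, leaving out library 31 kept 1488 of the 1909, but leaving out 4OHT library 22 kept 1397. Some calls may therefore be lost only because fewer libraries were tested. For those lost, a GC trend and an effect of 3DA cannot be told apart. In simulated counts with a GC trend in 1 library, 4OHT+3DA against 4OHT had 1 false call, and 0 with the correction. The Spearman correlation of fold changes with GC content was −0.485 there, against −0.315 observed. That simulation held no changed genes, and library 30 here had a trend besides library 31, so it does not settle the calls lost. Depth also differed, but 86.0% of calls stayed in the same direction after thinning, which argues against depth. An effect of 3DA stays open.

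The 4OHT+3DA levels of many genes lay between those of DMSO and 4OHT. A fixed share of cells with the DMSO profile, 22.1% to 30.5% from the mitosis list, could give this, and 43.0% of the 821 genes over 2-fold higher with 4OHT departed from its prediction (201 below and 152 above), between the bounds set, and 39.6% of the 1317 over 2-fold lower did (427 below and 95 above), with no bounds set. For the matrix list the upper quartile of the share was −1.17%, below the mitosis range, which argues against such a share for these genes. Lower HRAS expression is also open. With the GC correction HRAS was at −0.24 (SE 0.0506, n = 4 each, edgeR with Benjamini-Hochberg adjusted p = 0.00153), but the RAS-ERK list was not called (camera adjusted p = 0.359). With no filter on low counts and no GC correction that list was called lower (camera adjusted p = 0.0209). That setting compares the list with many genes of few reads, so its call is not weighed here. The genes that departed count against a fixed share as the whole cause of the levels between DMSO and 4OHT. For genes that kept to the prediction, neither such a share nor lower HRAS expression can be told apart from another effect of 3DA. A share of cells and the RNA of single cells were not measured.

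The log2 fold changes for 4OHT and for 3DA were negatively related, and both use the 4OHT libraries. With these split, the covariance was −0.165, outside the simulated −0.00244 to 0.00124. That argues against noise of single shared libraries as the whole cause. The simulation drew each library independently, and a deviation common to all 4OHT libraries would stay in both parts of a split. The test therefore cannot exclude such a deviation. An effect of 3DA on genes that changed with 4OHT is a candidate explanation. With no group given 3DA alone, it cannot be told apart from an effect of 3DA that does not depend on RAS.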

How the results depend on the processing

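The GC correction, with or without library 31, and the thinning were chosen after the data were seen. Of the values of the genes named in the text under other settings, 6445 stayed on their side of the threshold, 113 lost the call, 5 gained it and 6 reversed. For lists these were 1602, 47, 31 and 0. Many named genes were chosen for large changes without overlap, so their stability was partly fixed in advance. Of all 3558 genes called for 4OHT+3DA against 4OHT, 72.7% were kept with the GC correction and without library 31. Without 4OHT library 22 alone, 73.8% were kept. The 6 reversed values were of 2 genes not called in 4OHT+3DA against 4OHT: AHCY was at 0.0120 with library totals, 0.0243 with the GC correction, 0.0523 with that and without library 31 and 0.0199 without library 31 alone, and CDKN2B at −0.0693 without library 31 and −0.0348 with the GC correction too. Leaving out 1 library at a time gave −0.0980 to 0.0199 for AHCY and −0.0693 to 0.119 for CDKN2B. The cause was not tested.

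With an adjusted p under 0.01, 1944 genes were called for 4OHT+3DA against 4OHT and 1078 in opposite directions, from the stricter threshold itself. Leaving out 1 library gave 2719 to 3956 and 1453 to 1989. With an estimated correlation 26 of 47 lists were called, and 44 to 48 without 1 library. With no filter on low counts 62 lists were called, each compared with 30032 genes, many with few reads. Other counts of genes moved by less than 1.5 times under each setting run. No paired analysis was possible because the groups share no replicate numbers. With every library thinned to the lowest total, 6567, 3249 and 6419 genes were called for 4OHT against DMSO, 4OHT+3DA against 4OHT and 4OHT+3DA against DMSO, where the full counts gave 6889, 3558 and 6825.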

Other observations

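Some genes passed the test for 3DA only and not for 4OHT against DMSO: 727 were higher and 477 lower. With the GC correction and without library 31, settings chosen after the data were seen, 380 (52.3%) of the higher and 352 (73.8%) of the lower were kept. That the effect of 3DA differed from that of 4OHT for these genes was not tested.

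Set against the fixed share of cells described above, single genes departed in both directions. IL1B was at −2.11 (SE 0.10) where the share predicted −0.52 to −0.36, and CSF3 at −2.52 (SE 0.15) for a like prediction. The matrix gene DCN was at −0.0598 (SE 0.0703) where 1.15 to 1.42 was predicted, and CDKN2B at 0.0395 (SE 0.0949) where −0.48 to −0.33 was. MMP3 was at −0.15 (SE 0.0919) and DUSP6 at 0.10 (SE 0.0744). These genes were chosen after their values were seen. Median shares (quartiles over members more than 2-fold changed with 4OHT) were 26.6% (22.1% to 30.5%) for mitosis, 29.1% (20.04% to 37.1%) for replication, 46.0% (19.3% to 74.0%) for SASP cytokines, 24.4% (−0.897% to 37.1%) for SASP proteases and 23.99% (−22.9% to 43.9%) for SASP growth factors. They were 13.6% (−11.3% to 42.9%) for NF-kB targets, 15.8% (2.30% to 49.0%) for CDK inhibitors, 18.9% (11.2% to 44.3%) for lamina and HMG genes, 26.5% (13.7% to 49.9%) for the RAS-ERK list and 17.9% (14.5% to 38.0%) for histone genes. The others were 29.3% (−8.89% to 50.9%) for the ATF4 response, 3.60% (−1.44% to 22.1%) for interferon, 46.0% (45.0% to 51.3%) for lysosome and −7.34% (−22.2% to −1.17%) for matrix genes. The quartile range missed that of mitosis for lysosome, with 5 genes, and for matrix genes, with 14.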
